A study of Mus musculus with 12 samples.

How the data were processed

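Gene expression was measured by poly(A) RNA sequencing in 12 libraries of bone-marrow monocytes from WT and Nr4a3 KO mice, sorted or cultured for 1 or 2 days with GM-CSF and IL-4. Per the labels' protocols, libraries were made with a stranded mRNA kit from 20 ng of total RNA with 16 PCR cycles and sequenced on a HiSeq 2000. Per the submitters' processing notes, the tools were Trimmomatic 0.35 for reads and STAR 2.5.1b for alignment to GRCm38. The annotation release the authors used is not given in the sources used here.

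The deposited values are whole-number read counts per gene in the layout of STAR's gene counting, 1 file per library, with no normalization by the authors. Column 4, the counts for a reverse-stranded kit, was used throughout. Reads on the other strand of genes made up 3.63% to 5.33% of the reads counted in genes on both strands. The files list 47643 gene IDs, of which 47224 matched a symbol in the GENCODE M21 annotation of GRCm38, which also gave coordinates. The 4 lines of each file that name no gene were kept out of library sizes and tests. Of all reads they held between 2.65% and 7.91% as unmapped, 5.29% to 8.94% as multimapping, 5.24% to 11.2% outside genes and 1.34% to 1.76% as ambiguous. Multimapping reads were not counted, so genes with near-identical copies are undercounted.

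Depth ran from 5905266 reads in genes (KO day 2 replicate 1) to 18447405 (KO day 1 replicate 2), and a count of 0 was read as up to 3 counts. No library pair was within sampling noise, with a smallest chi-square per degree of freedom of 11.1 over genes with a summed count of at least 20. Groups and replicate numbers came from the labels, which state independent experiments. No label says how many mice gave cells to a library.

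Genes were tested with edgeR 4.0.16 in R 4.3.3 (files read with the data.table package, version 1.17.8). The fit used TMM normalization, filterByExpr on the groups, robust quasi-likelihood dispersion and 1 mean per group over all 12 libraries, with 6 residual degrees of freedom. It tested 14034 genes, with a common biological coefficient of variation of 0.393 and a median of 4.61 prior degrees of freedom. There were 7 contrasts (KO against WT at the 3 stages, and days 1 and 2 against monocytes in each genotype) and 3 interaction contrasts. Tests were two-sided with Benjamini-Hochberg adjustment over all genes, at an adjusted p threshold of 0.05.

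In total 33 gene lists were fixed before the data were examined, covering NR4A genes, dendritic cell identity and maturation, MHC class II, monocyte and macrophage genes, cytokine and stress responses, metabolism and markers of other cells. They were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01, adjusted over the lists of a contrast. Lists share genes, with 7 of the 22 maturation genes and 15 of the 27 IL-4 response genes also in another list. List medians were also computed with genes at 0 reads in 1 group set to their bound. Genes changed at least 4-fold in WT cells by culture (a log2 fold change of 2, alternative 1) formed lists tested in the genotype comparison at the other day.

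The rule for named genes was fixed at the same time. In each contrast it took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM and the same direction in both pairs. Predicted or clone-named genes, ribosomal protein pseudogenes and receptor segments were left out. It added the 3 NR4A genes, up to 4 members of a described list with the smallest adjusted p that passed, and up to 2 with the highest mean CPM that did not. Interactions took the 6 genes with the smallest adjusted p. Fewer are printed, some are not reported here, and exceptions are stated where they occur.

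Libraries with the same number at a stage share an experiment, by the dates in the names of the deposited files. There were 4 experiments, 2 for monocytes and day 1 and 2 for day 2. Deviations from the group means of same-numbered KO and WT libraries correlated across genes at 0.236 in monocytes, 0.194 at day 1 and 0.657 at day 2. For day 1 replicate 2 those names say 16 hours where the labels say 1 day.

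Alternatives fixed beforehand were RLE and upper-quartile normalization, no low-count filter, a replicate block by experiment or by number alone, DESeq2 1.42.0, a fit on the compared groups only, an estimated correlation or fry for lists, the lower list threshold and leaving out each library. Chosen after seeing the data were unstranded counts and leaving out both libraries that stood apart (WT monocytes replicate 2 and the library labelled KO day 1 replicate 1), also with the block. A paired fit on the compared groups only (for lists also with an estimated correlation) was chosen then too. So was a crossed split of the day 2 libraries, whose sides each mix KO and WT. List medians without the libraries that stood apart came from edgeR on the same 14034 genes. Leaving both out left 1 library in WT monocytes and 1 in KO day 1, whose spread was taken from the other groups.

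The tests were tried on simulated counts with 200 genes changed. For KO against WT at day 2, edgeR on all libraries recovered 1.43% of genes changed 2-fold, 40.6% at 4-fold and 84.8% at 8-fold, with 7 false calls of 13363 genes. The paired fit recovered 96.9% at 2-fold and 100% at 4-fold and 8-fold, with 35 false calls of 12251 genes. The paired simulation took its spread from the paired fit on the same libraries, with no variation of the genotype effect between experiments. Its figures therefore cannot show how reliable the paired calls in the data are. For WT day 1 against monocytes the shares were 0%, 57.3% and 91.4%, with 2 false calls of 13037 genes.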

Results

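Poly(A) RNA was sequenced from bone-marrow monocytes of wild-type mice (WT) and of mice lacking Nr4a3 (KO), which encodes an orphan nuclear receptor of the NR4A family. The cells were taken straight after sorting or were kept for 1 or 2 days with GM-CSF and IL-4, a cytokine pair widely used to turn monocytes into dendritic cells in culture. The series title names the question, which is the part NR4A3 plays in that differentiation. The 12 libraries form 6 groups of 2, and per the labels the members of a group came from independent experiments. The reads counted in genes, for replicates 1 and 2 in turn, were 12961706 and 10687668 in WT monocytes and 13764588 and 14431691 in KO monocytes. They were 11996973 and 12185629 in WT day 1, 10733224 and 18447405 in KO day 1, 8770888 and 7787493 in WT day 2, and 5905266 and 12116249 in KO day 2. Levels are given in CPM, gene counts scaled to the TMM-adjusted library size, with the mean ± SD of n = 2 libraries, and log2 fold changes with ± SE from edgeR.

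The libraries separated first by stage of culture, and 2 of them stood apart. The first principal component of log2 CPM held 52.9% of the variance and the second 17.5%. The library labelled KO day 1 replicate 1 scored 1.59 on the first, against 38.4 to 46.7 for the other 3 day 1 libraries and -139.8 to -115.5 for the monocytes. In WT monocytes replicate 2, ribosomal protein genes took 8.38% of gene reads, against 3.81% to 4.70% in the other 3 monocyte libraries. Markers of neutrophils summed to 4511 CPM in it, against 1810 to 2975 CPM in those 3. The Spearman correlation across genes, which are not independent replicates, was 0.937 between the WT monocyte libraries and 0.978 between the KO monocyte libraries. Xist, the RNA of the inactive X chromosome, stood at 885 CPM in WT day 2 replicate 1 and 794 CPM in KO day 2 replicate 1, which share an experiment. It stood at no more than 1.01 CPM in the other 10 libraries. Ddx3y, a gene of the Y chromosome, had 0 reads and 1 read in those 2 libraries and 34.5 to 98.2 CPM in the other 10. By these genes the cells of that experiment were female and those of the other experiments male.

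Nr4a3 itself (ENSMUSG00000028341.9, GRCm38 chromosome 4, 48045153 to 48086447) was close to silent in monocytes and abundant in WT cells at day 2. WT monocytes held 4 reads of Nr4a3 (0.307 CPM) in replicate 1 and 0 in replicate 2, and KO monocytes 13 reads (0.928 CPM) and 0. In WT cells Nr4a3 reached 16.5 and 10.4 CPM at day 1 and 1287 and 1358 CPM at day 2. KO day 2 libraries held 39.0 and 19.3 CPM of Nr4a3, a log2 fold change of -5.51 ± 1.36 against WT (edgeR adjusted p = 0.389). A fit that pairs the day 2 libraries by experiment, an alternative chosen after seeing the data, gave Nr4a3 -5.59 ± 0.37 (edgeR adjusted p = 0.00662). KO day 1 replicate 2 held 0 reads of Nr4a3, which allows up to 0.164 CPM, but the library labelled KO day 1 replicate 1 held 76 reads (6.58 CPM). That value is unlike KO day 1 replicate 2 and leaves the label in doubt. It does not decide the label, since the KO day 2 libraries held Nr4a3 reads too. Every direction drawn from this library at day 1 carries that doubt. Whether the remaining reads lie in the deleted part of the gene is not known from gene counts. From monocytes, Nr4a3 rose in WT cells by 6.19 ± 1.75 at day 1 (edgeR adjusted p = 0.0298) and by 12.81 ± 1.97 at day 2 (adjusted p = 0.00137). Its day 1 call in WT cells was lost without any 1 of the 4 libraries: Nr4a3 had adjusted p = 0.0666 without WT monocytes replicate 1, 0.111 without WT monocytes replicate 2, 0.0985 without WT day 1 replicate 1 and 0.0700 without WT day 1 replicate 2. In KO cells Nr4a3 rose by 5.94 at day 2 (edgeR adjusted p = 0.0234), with adjusted p = 0.0635 without KO monocytes replicate 1, 0.163 without KO monocytes replicate 2 and 0.0733 without KO day 2 replicate 1. The related Nr4a1 fell in WT cells from 468 ± 504 CPM in monocytes to 0.977 ± 0.406 CPM at day 2 (-8.90 ± 1.13, adjusted p = 0.000463). In KO cells Nr4a1 fell by 7.87 ± 1.05 (adjusted p = 0.000843). Nr4a2 at day 2 was 12.04 ± 2.87 CPM in KO and 11.4 ± 1.28 CPM in WT cells (0.08 ± 1.31, adjusted p = 1). As a list, the 3 NR4A genes passed in no comparison, with a lowest camera adjusted p of 0.100. The NR4A list was called in KO day 1 against monocytes without the 2 libraries that stood apart (median -5.49, or -3.69 with genes at 0 at their bound, camera adjusted p = 0.0379; adjusted p = 0.426 with an estimated correlation).

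**Figure D1:**
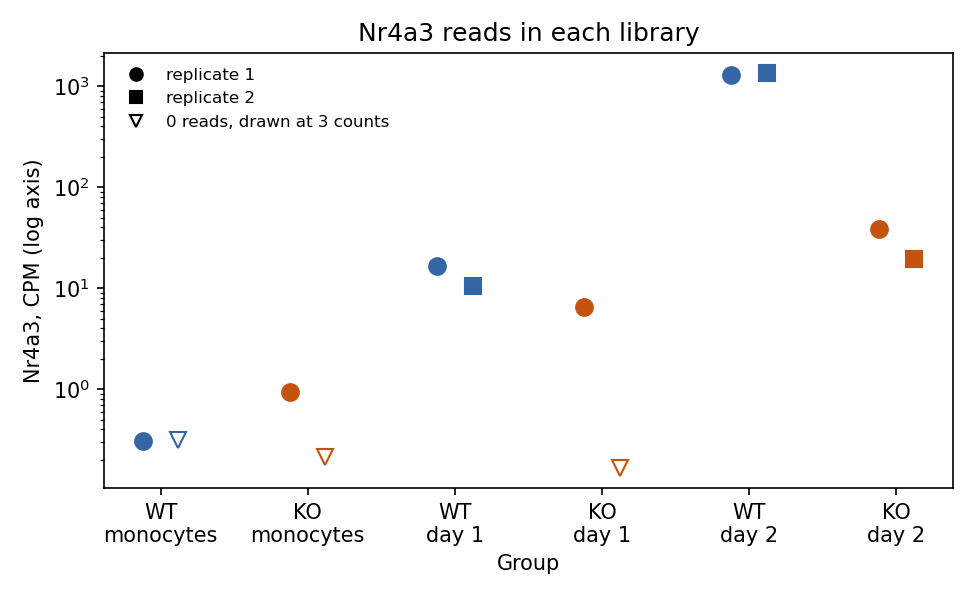
Nr4a3 in CPM on a log axis, 1 point per library for the 6 groups of 2, with libraries at 0 reads drawn as open triangles at the level of 3 counts. WT day 2 libraries lie at 1287 and 1358 CPM and KO day 2 libraries at 39.0 and 19.3 CPM, and the library labelled KO day 1 replicate 1 lies at 6.58 CPM.

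Within 1 day of culture, WT monocytes lost monocyte genes and gained genes of dendritic cells, antigen presentation and cytokine response. F13a1, a coagulation factor subunit of classical monocytes, fell from 3582 ± 339 to 62.0 ± 16.7 CPM (-5.85 ± 0.42, edgeR adjusted p = 3.37e-05). Itgax, the integrin CD11c of dendritic cells, rose from 2.63 ± 0.903 to 1453 ± 267 CPM (9.12 ± 0.58, adjusted p = 2.77e-05). Cd74, the invariant chain of MHC class II, rose from 139.5 ± 5.41 to 5239 ± 1340 CPM (5.23 ± 0.40, adjusted p = 4.29e-05). The STAT target Cish rose by 9.69 ± 0.63 and the elastase gene Mmp12 by 10.88 ± 0.99 (adjusted p = 2.77e-05 and 0.000138). Ccr2, the chemokine receptor that marks classical monocytes, was 2245 ± 739 CPM before and 2171 ± 453 CPM after (-0.05 ± 0.51, adjusted p = 0.968). Chil3 was 2805 ± 1820 and 2896 ± 1200 CPM (0.05 ± 0.88, adjusted p = 0.988).

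The gene lists moved in the same terms at WT day 1, and each is given with its median log2 fold change and camera adjusted p. With an estimated correlation the GM-CSF response alone stayed under the threshold (adjusted p = 0.00783), and the other lists called had adjusted p = 0.168 or more with an estimated correlation. Of 20 classical monocyte genes, 14 fell and 1 rose (-3.34, 5.64e-07, and 14 and 1 adjusted over the list alone). Of 15 nonclassical monocyte genes, 7 fell and 2 rose (-1.995, 0.0154, and 8 and 3 adjusted over the list alone). Genes of the GM-CSF response rose in 16 of 20 (5.02, or 5.01 with genes at 0 set to their bound, 1.69e-11, and 16 adjusted over the list alone). Those of the IL-4 response rose in 17 of 27 and fell in 1 (4.29, or 4.97 with genes at 0 at their bound, 2.92e-08, and 21 and 1 adjusted over the list alone). Dendritic cell identity had 13 of 26 higher and 4 lower (2.30, 0.00145, and 16 and 5 adjusted over the list alone), and MHC class II 8 of 14 higher and 1 lower (2.81, 0.00131, and 8 and 1 adjusted over the list alone). Dendritic cell maturation had 10 of 22 higher and 1 lower (3.39, or 2.31 with genes at 0 at their bound, 2.56e-05, and 12 and 1 adjusted over the list alone). The unfolded protein response rose in 10 of 18 genes (1.72, 6.68e-06, and 11 adjusted over the list alone). Its members Creld2 and Calr, a chaperone of the endoplasmic reticulum, rose by 3.36 ± 0.45 and 1.98 ± 0.30 (edgeR adjusted p = 0.000879 and 0.00163). Cell cycle genes fell in 25 of 38 (-1.63, 1.18e-12, and 30 adjusted over the list alone). Ccnb2, cyclin B2, was at -3.15 ± 0.35 (edgeR adjusted p = 0.000393). Interferon-stimulated genes fell in 16 of 37 (-2.40, 2.17e-08, and 21 adjusted over the list alone), with Ifi47 at -3.62 ± 0.78 (edgeR adjusted p = 0.00919). Other lists past the threshold were p53 targets (1.64, or 1.36 with genes at 0 at their bound, 0.00937), matrix proteases (3.41, or 2.29, 0.00447) and inflammatory NF-kB targets (1.59, 0.0464).

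Markers of other cells moved beside these lists at WT day 1. Erythroid genes fell in 5 of 9 (median -8.04, or -4.39 with genes at 0 at their bound, camera adjusted p = 6.67e-06, and 6 adjusted over the list alone), and stromal genes in 2 of 7 (-1.96, or -1.85, 0.0276, and 3 adjusted over the list alone). Neutrophil genes fell in 6 of 20 and rose in 2 (-0.72, 0.0083, and 6 and 2 adjusted over the list alone). Mpo, a granule protein gene of neutrophil and monocyte precursors, fell from 161 ± 9.74 to 2.17 ± 0.62 CPM (-6.21 ± 0.41, edgeR adjusted p = 2.77e-05). Without the 2 libraries that stood apart, the neutrophil median was 0.47, or 0.35 with genes at 0 at their bound, while camera still tested it as lower (adjusted p = 0.274). Without them the stromal median was -0.86, or -1.19 (camera adjusted p = 0.101), and the inflammatory NF-kB median 1.81 (camera adjusted p = 0.101), and with the replicate block the stromal adjusted p was 0.0502. edgeR called 1598 genes higher and 1424 lower of 14034 tested. The higher count was 1063 without WT monocytes replicate 2, 789 without WT day 1 replicate 1 and 844 without WT day 1 replicate 2, and the lower count 608 and 612 without those same day 1 libraries in turn.

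Genes that rose in WT cells over 2 days included Aldh1a2, Fscn1, Il7r, Ccl22 and H2-Eb1. Aldh1a2, which makes retinoic acid, had no reads in WT monocytes and 1869 ± 719 CPM at day 2, at least 14215-fold higher (edgeR adjusted p = 0.000351). Fscn1, the actin-bundling protein fascin of mature dendritic cells, was at least 6449-fold higher at 865 ± 189 CPM (adjusted p = 0.00416). Il7r was at least 1172-fold higher at 152.5 ± 104 CPM (adjusted p = 0.000273). These bounds set the group at 0 to 3 counts over the group. The chemokine Ccl22 rose from 1.34 ± 0.0483 to 13359 ± 3700 CPM (13.28 ± 0.92, adjusted p = 2.33e-05). H2-Eb1, an MHC class II chain, rose from 10.4 ± 5.10 to 2843 ± 610 CPM (8.10 ± 0.58, adjusted p = 2.47e-05), and Traf1, an adaptor of TNF receptor signalling, from 0.220 ± 0.0134 to 394 ± 44.3 CPM (10.73 ± 0.41, adjusted p = 6.43e-07). Plac8 (-8.62 ± 1.11), of classical monocytes, and Fos (-7.79 ± 1.10), an immediate early gene, fell (adjusted p = 0.000514 and 0.000835). Pdcd1lg2, the inhibitory ligand PD-L2, rested on 1 read in WT monocytes, and its ratio was 9145 with a 95% Poisson interval of 1641 to 361218. Intervals and bounds of this kind cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

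All 22 dendritic cell maturation genes had positive values at WT day 2, and 20 rose (median 7.72, or 6.21 with genes at 0 at their bound, camera adjusted p = 2.11e-14, and 21 adjusted over the list alone). With an estimated correlation the GM-CSF response had adjusted p = 0.0168 and every other list adjusted p = 0.0827 or more. Dendritic cell identity rose in 14 of 26 genes (2.99, 7.27e-06, and 16 adjusted over the list alone) and MHC class II in 7 of 14 with 1 lower (1.97, 0.000162, and 7 and 1 adjusted over the list alone). The GM-CSF response rose in 14 of 20 (7.08, 4.73e-09, and 16 adjusted over the list alone). The IL-4 response rose in 16 of 27 with 2 lower (4.26, 1.88e-05, and 18 and 2 adjusted over the list alone). Cholesterol synthesis rose in 16 of 22 (1.87, 1.23e-06, and 17 adjusted over the list alone), with Hmgcs1 at 2.35 ± 0.31 and Cyp51 at 2.30 ± 0.32 (edgeR adjusted p = 0.000523 and 0.000817). Lipid handling (1.92, 0.0264), p53 targets (1.54, 0.00254), matrix proteases (3.54, or 3.19 with genes at 0 at their bound, 0.00627) and inflammatory NF-kB targets (2.77, or 2.46, 0.00898) also had positive medians past the threshold. Cell cycle genes fell in 26 of 38 (-1.70, 5.70e-14, and 30 adjusted over the list alone), with Kif23 at -2.96 ± 0.34 (edgeR adjusted p = 0.000278). Classical monocyte genes fell in 14 of 20 (-4.33, 2.54e-09, and 14 with 1 higher adjusted over the list alone) and nonclassical monocyte genes in 8 of 15 with 3 higher (-2.56, 0.0212, and 8 and 4 adjusted over the list alone). Interferon-stimulated genes fell in 10 of 37 (-1.71, 0.000229, and 10 adjusted over the list alone), and neutrophil markers moved beside them with 8 of 20 lower and 2 higher (-2.24, 0.000119, and 11 and 3 adjusted over the list alone). The neutrophil median was -1.15 (camera adjusted p = 0.0158) without the 2 libraries that stood apart. Immediate early genes had a median of -0.61, or -0.82 with genes at 0 at their bound (camera adjusted p = 0.107), and of -1.33, or -1.58, in that fit (camera adjusted p = 0.0121; adjusted p = 0.687 with an estimated correlation over all libraries). edgeR called 1778 genes higher and 1388 lower. The higher count was 2690 without WT monocytes replicate 1, 1123 without WT monocytes replicate 2, 1082 without WT day 2 replicate 1 and 972 without WT day 2 replicate 2, and the lower count 741 and 522 without those day 2 libraries. Day 2 cultures came from other experiments than the monocytes, so day and experiment cannot be told apart here. By Xist and Ddx3y, day 2 replicate 1 also differs from the monocytes in sex.

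KO cells were asked the same question against their own monocytes, and the 16 lists called in WT cells at day 1 passed in KO cells too, with immediate early genes besides. In WT cells at day 1 immediate early genes had a median of -0.94 (camera adjusted p = 0.268), and -1.37 (camera adjusted p = 0.0472; adjusted p = 0.907 with an estimated correlation over all libraries) without the 2 libraries that stood apart. Itgax rose from 2.52 ± 1.04 to 845 ± 343 CPM (8.38 ± 0.56, edgeR adjusted p = 4.67e-05) and Cd74 from 180 ± 2.96 to 5227 ± 1610 CPM (4.86 ± 0.39, adjusted p = 7.94e-05). Cish rose by 8.12 ± 0.57 and Traf1 by 4.69 ± 0.30 (both adjusted p = 4.67e-05). F13a1 fell by 5.82 ± 0.42 (adjusted p = 4.67e-05) and the phosphatase gene Dusp1 of the immediate early list by 4.96 ± 0.59 (adjusted p = 0.000715). Creb5, a transcription factor with no reads in KO monocytes, was at least 999-fold higher at 102 ± 28.4 CPM (adjusted p = 4.67e-05). The GM-CSF response rose in 15 of 20 genes (median 5.62, or 5.26 with genes at 0 at their bound, camera adjusted p = 3.99e-11, and 15 adjusted over the list alone). It had adjusted p = 0.00859 with an estimated correlation, and every other list adjusted p = 0.112 or more. The IL-4 response rose in 16 of 27 with 1 lower (4.79, or 4.05 with genes at 0 at their bound, 1.20e-07, and 21 and 2 adjusted over the list alone). MHC class II rose in 8 of 14 (2.92, 1.92e-06, and 9 adjusted over the list alone). Dendritic cell identity rose in 13 of 26 with 3 lower (3.23, 5.46e-05, and 19 and 5 adjusted over the list alone). Dendritic cell maturation rose in 6 of 22 (2.49, or 2.42 with genes at 0 at their bound, 4.91e-05, and 13 adjusted over the list alone). Without the library labelled KO day 1 replicate 1 and WT monocytes replicate 2 the maturation median was 0.68 (camera adjusted p = 0.0379). Cell cycle genes fell in 28 of 38 (-1.70, 1.09e-17, and 33 adjusted over the list alone) and classical monocyte genes in 8 of 20 (-2.76, 1.02e-06, and 12 with 1 higher adjusted over the list alone). Nonclassical monocyte genes fell in 6 of 15 with 1 higher (-2.45, 0.000411, and 9 and 2 adjusted over the list alone) and immediate early genes in 9 of 22 with 4 higher (-1.51, 0.00659, and 11 and 5 adjusted over the list alone). The interferon-stimulated list had a median of -0.93 (camera adjusted p = 3.28e-05) with none of 37 genes called over all genes or adjusted over the list alone. Without the same 2 libraries its median was -2.69 (camera adjusted p = 2.41e-10). The unfolded protein response (1.53, 1.92e-06), p53 targets (1.54, 0.00156), matrix proteases (2.12, or 1.36 with genes at 0 at their bound, 0.00391) and inflammatory NF-kB targets (1.31, or 1.37, 0.0194) also passed. Without those 2 libraries the matrix protease median was 0.84 (camera adjusted p = 0.0446) and the inflammatory NF-kB median 0.96, or 1.52 with genes at 0 at their bound (camera adjusted p = 0.111). Beside them moved markers of neutrophils (-1.04, or -1.09 with genes at 0 at their bound, 0.000132), erythroid cells (-7.29, or -4.06, 2.16e-06) and stroma (-2.01, 0.00942). Without those 2 libraries the neutrophil median was -1.81, or -1.89 (camera adjusted p = 0.000546), and the stromal median -3.47, or -2.08 (camera adjusted p = 0.0446). edgeR called 1081 genes higher and 861 lower at day 1, 1734 and 1574 without the same 2 libraries, and 1419 lower with the replicate block. The higher and lower counts were 348 and 315 without KO monocytes replicate 1, 303 and 297 without KO monocytes replicate 2, and 446 and 276 without KO day 1 replicate 2.

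At day 2, KO cells had 4310 ± 1100 CPM of Ccl22 against 0.853 ± 0.298 CPM in KO monocytes (12.28 ± 0.89, edgeR adjusted p = 3.40e-05). Mmp12 rose by 12.60 ± 1.03 (adjusted p = 5.47e-05) and H2-Eb1 by 8.96 ± 0.60 (adjusted p = 1.94e-05). Itgae, the integrin CD103, was at least 2009-fold and Tnfrsf9, the costimulatory receptor 4-1BB, at least 1788-fold higher than in KO monocytes, which held no reads of either (edgeR adjusted p = 0.000619 and 0.000854). Prtn3, proteinase 3 of granules, fell from 247 ± 19.0 to 0.533 ± 0.518 CPM (-8.61 ± 0.53, adjusted p = 1.84e-05). Dendritic cell maturation rose in 19 of 22 genes with 1 lower (median 5.48, or 4.68 with genes at 0 at their bound, camera adjusted p = 1.01e-10, and 20 and 1 adjusted over the list alone). With an estimated correlation the GM-CSF response had adjusted p = 0.0131 and the other lists adjusted p = 0.0634 or more. Dendritic cell identity rose in 16 of 26 (3.51, 1.45e-07, and 18 and 1 adjusted over the list alone) and MHC class II in 9 of 14 (3.37, 3.00e-07, and 10 adjusted over the list alone). The GM-CSF response rose in 14 of 20 (6.60, 7.08e-10, and 15 and 1 adjusted over the list alone). The IL-4 response rose in 16 of 27 with 2 lower (5.69, or 4.60 with genes at 0 at their bound, 3.57e-07, and 20 and 2 adjusted over the list alone). Cholesterol synthesis rose in 11 of 22 (1.26, 5.10e-06, and 14 adjusted over the list alone) and matrix proteases in 8 of 16 (3.36, 0.000116, and 9 adjusted over the list alone). The medians of inflammatory NF-kB targets (2.73, or 2.72 with genes at 0 at their bound, 0.000217), p53 targets (1.35, 0.00181) and the unfolded protein response (0.56, 0.0237) were positive past the threshold. Eosinophil markers moved beside them (2.81, 0.0369). The medians of classical monocyte (-3.90, 1.71e-10), nonclassical monocyte (-2.39, 0.00121), cell cycle (-1.78, 4.76e-15), interferon-stimulated (-0.86, 0.00207), immediate early (-0.73, 0.0279) and neutrophil genes (-1.32, 0.00121) were negative. edgeR called 1396 genes higher and 1063 lower, with 1618 lower under the replicate block and 1844 lower without the library labelled KO day 1 replicate 1 and WT monocytes replicate 2. The higher and lower counts were 664 and 560 without KO monocytes replicate 1 and 527 and 435 without KO monocytes replicate 2. They were 875 and 476 without KO day 2 replicate 1 and 738 and 400 without KO day 2 replicate 2. As in WT cells, day 2 and its experiments, with the other sex in replicate 1, cannot be told apart.

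**Figure D2:**
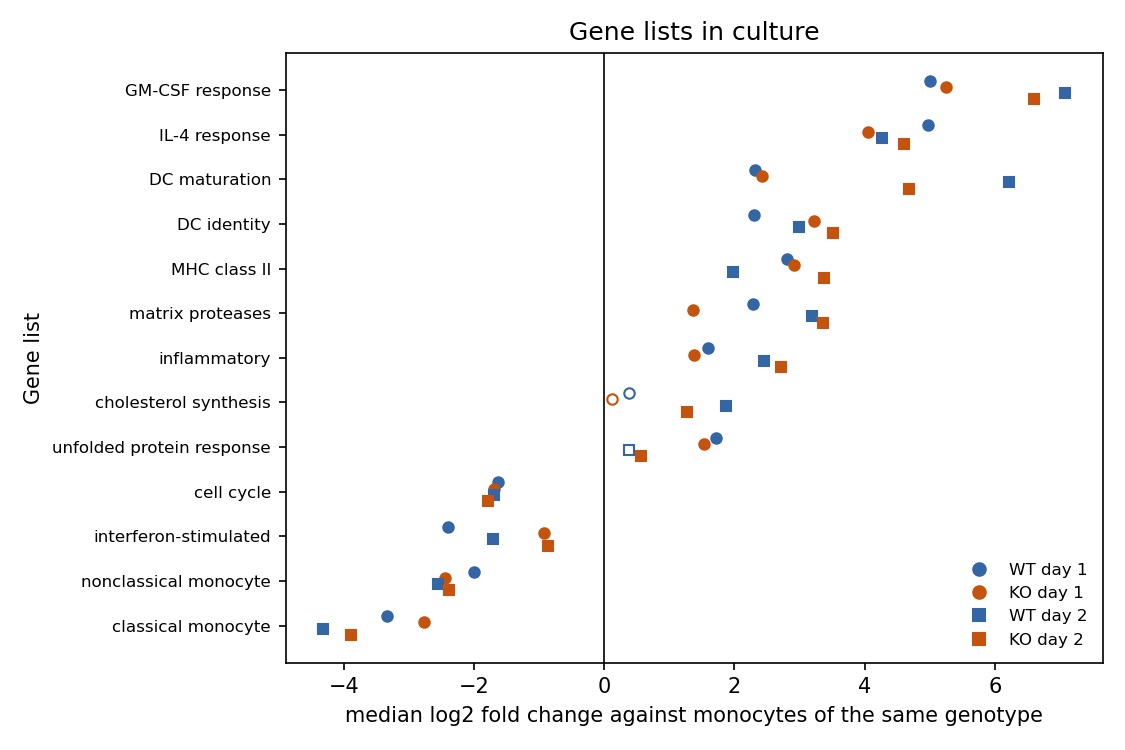
Median log2 fold change against monocytes of the gene lists at days 1 and 2 in WT and KO cells, with genes at 0 set to their bound and open symbols for lists with a camera adjusted p at or over the threshold. Dendritic cell maturation reaches 6.21 in WT and 4.68 in KO cells at day 2, and cell cycle lies at -1.70 and -1.78.

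Sorted KO and WT monocytes, compared to ask whether the genotypes differ before culture, could not be separated gene by gene over all libraries. Nr4a1 was 489.9 ± 301 CPM in KO and 468 ± 504 CPM in WT monocytes (0.07 ± 0.76, edgeR adjusted p = 1) and Nr4a2 12.8 ± 12.1 and 5.98 ± 8.45 CPM (1.08 ± 1.32, adjusted p = 1). Platelet markers formed the 1 list past the threshold, with a median of -1.99 over 5 genes (camera adjusted p = 0.0286). The platelet list had adjusted p = 0.0595 with the replicate block and adjusted p = 0.982 with an estimated correlation. Itga2b, the platelet integrin chain CD41, was 1.57 ± 0.0927 CPM in KO against 6.28 ± 2.16 CPM in WT monocytes (-1.99 ± 0.82, edgeR adjusted p = 0.998). No platelet gene passed over all genes, and 1 was lower adjusted over the list alone. edgeR called 0 genes higher and 0 lower of 14034, with 557 at an unadjusted p under 0.05 where 702 are expected by chance, and DESeq2 called 0 and 0. A fit that pairs the monocyte libraries by experiment, chosen after seeing the data, called 2 higher and 3 lower of 12101. Without WT monocytes replicate 1 edgeR called 123 higher and 14 lower. Lists called numbered 2 without WT monocytes replicate 1, KO monocytes replicate 1 or KO monocytes replicate 2, and 4 without WT monocytes replicate 2. Without both libraries that stood apart, neutrophil markers were higher in KO (0.77, camera adjusted p = 0.0149), as were oxidative phosphorylation (0.35, camera adjusted p = 0.000644) and cell cycle genes (0.25, camera adjusted p = 0.00338). That fit holds 1 WT monocyte library. Over all libraries the medians were -0.02, -0.14 and 0.22 in turn, so the first 2 changed sign. All 3 lists had adjusted p = 0.982 with an estimated correlation over all libraries.

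At day 1, interferon-stimulated genes had a median of 1.21 in KO against WT (camera adjusted p = 2.68e-06; adjusted p = 0.864 with an estimated correlation), a value that rested on the library labelled KO day 1 replicate 1. The pairs by experiment gave the interferon-stimulated list 3.11 and -1.07. Without the 2 libraries that stood apart, which leaves 1 KO library at day 1, its median was -0.62. Slfn5, an interferon-induced gene, was 188 ± 228 CPM in KO and 62.2 ± 30.9 CPM in WT cells (1.59 ± 0.88, edgeR adjusted p = 1). The IL-4 response list had a median of -0.56 (camera adjusted p = 2.21e-06; adjusted p = 0.726 with an estimated correlation), with pairs at -1.46 and -0.05. Without the 2 libraries the IL-4 response had a median of -0.11 (camera adjusted p = 0.672). Within it, Ccl17, a chemokine of dendritic cells, was 1253 ± 1580 CPM in KO and 2153 ± 1050 CPM in WT cells (-0.78 ± 0.92, edgeR adjusted p = 1). Eosinophil markers, mostly Alox15, which IL-4 also induces, summed to 0.652 CPM in the library labelled KO day 1 replicate 1 and to 57.2 to 102 CPM in the other 3 day 1 libraries. Macrophage genes had a median of 0.49 (camera adjusted p = 0.00123; adjusted p = 0.864 with an estimated correlation), with Csf1r, the M-CSF receptor, at 1247 ± 487 and 1058 ± 316 CPM (0.24 ± 0.47, edgeR adjusted p = 1). The macrophage median without the 2 libraries was -0.05 (camera adjusted p = 0.612).

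Dendritic cell maturation genes had a median of -0.23 in KO against WT cells at day 1 (camera adjusted p = 0.022; adjusted p = 0.864 with an estimated correlation). The pairs gave dendritic cell maturation 0.25 and -0.39. Without the 2 libraries, which leaves 1 KO library at day 1, its median was -0.31. In that fit neutrophil markers were lower in KO as well (-1.13, or -1.05 with genes at 0 at their bound, camera adjusted p = 0.0166; adjusted p = 0.949 with an estimated correlation over all libraries). They summed to 991 CPM in KO day 1 replicate 2 against 1297 and 2380 CPM in the WT day 1 libraries. Tmem123 was 235.5 ± 37.5 CPM in KO and 204 ± 32.2 CPM in WT cells (0.21 ± 0.39, edgeR adjusted p = 1), and Birc3, an inhibitor of apoptosis, 168 ± 22.4 and 141 ± 34.2 CPM (0.25 ± 0.36, adjusted p = 1). No member of these 4 lists passed, over all genes or adjusted over the list alone. edgeR called 0 genes higher and 0 lower at day 1, with 252 at an unadjusted p under 0.05 against 702 expected, and DESeq2 called 1 higher and 0 lower. Without KO day 1 replicate 2, which leaves the doubted library alone in its group, edgeR called 15 higher and 10 lower and camera 9 lists. Lists called numbered 10 without WT day 1 replicate 1 and 7 with the replicate block, which added classical monocyte (0.42, camera adjusted p = 0.0333), lysosome (0.29, 0.0199) and eosinophil genes (-0.87, 0.0333). These had adjusted p = 0.864, 0.880 and 0.864 with an estimated correlation in turn.

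At day 2, edgeR over all libraries called a small set of genes lower in KO than in WT cells. Slc4a8, a sodium-coupled bicarbonate transporter (ENSMUSG00000023032.12, chromosome 15, 100761747 to 100823968), was 0.414 ± 0.122 CPM in KO and 93.4 ± 5.49 CPM in WT cells (-7.86 ± 0.69, edgeR adjusted p = 0.00383). Scd1, the desaturase that makes monounsaturated fatty acids (ENSMUSG00000037071.2, chromosome 19, 44394455 to 44407879), was 26.4 ± 5.78 against 223 ± 7.38 CPM (-3.07 ± 0.35, adjusted p = 0.0249). Map3k14, the kinase NIK of noncanonical NF-kB signalling (ENSMUSG00000020941.7, chromosome 11, 103219762 to 103267472), was 44.2 ± 15.3 against 365 ± 33.1 CPM (-3.05 ± 0.38, adjusted p = 0.0249). Samsn1, an adaptor protein (ENSMUSG00000022876.17, chromosome 16, 75858793 to 76022281), was 30.9 ± 17.8 against 388 ± 36.5 CPM (-3.66 ± 0.52, adjusted p = 0.0305). Anxa3 (-2.57 ± 0.34, adjusted p = 0.0285), Rabgap1l (-2.67 ± 0.37, 0.0305), Nudt17 (-4.68 ± 0.69, 0.0388) and Adcy6, an adenylyl cyclase (-4.82 ± 0.72, 0.0429), also fell. Slc4a8 had adjusted p = 0.0708 without KO day 2 replicate 2. The calls of the other 7 were lost without any 1 of the day 2 libraries, with the lowest adjusted p at 0.0664 for Samsn1 without KO day 2 replicate 1 and the highest at 0.530 for Adcy6 without KO day 2 replicate 2. Adcy6 had adjusted p = 0.0745 with the replicate block and 0.0554 on unstranded counts, and Nudt17 0.0585 in the paired fit on the day 2 libraries. With only the day 2 groups fitted, Slc4a8 and Adcy6 kept their calls and the other 6 had adjusted p from 0.102 (Anxa3) to 0.315 (Samsn1). Aldh1a2 lies outside the rule for named genes in this comparison and was chosen after its values were seen. It was 7.997 ± 10.4 CPM in KO and 1869 ± 719 CPM in WT cells (-7.94, edgeR adjusted p = 0.0545, and DESeq2 adjusted p = 2.2e-06). With the replicate block Aldh1a2 had adjusted p = 0.0455, without KO day 2 replicate 1 adjusted p = 0.00234 and without KO day 2 replicate 2 adjusted p = 0.0326.

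edgeR called 14 genes lower and 0 higher in KO at day 2, with 444 of 14034 at an unadjusted p under 0.05 where 702 are expected, and DESeq2 called 83 lower and 1 higher. Across genes, day 2 libraries of the same experiment had Spearman correlations of 0.980 and 0.971 between genotypes. Replicates of a genotype had 0.969 in WT and 0.966 in KO cells. That edgeR fit takes no account of experiment, so its few calls do not show that few genes differ. Without WT day 2 replicate 1, WT day 2 replicate 2 or KO day 2 replicate 2 the lower count was 1, and without KO day 2 replicate 1 it was 2. The lower count was 35 with the replicate block and 44 without the 2 libraries that stood apart. A fit on the 4 day 2 libraries with the experiment as a block, chosen after seeing the data and with 1 residual degree of freedom, called 764 genes higher and 794 lower of 12233. A crossed split of the same libraries, whose sides each mix KO and WT, called 0 and 0, with 15 at an unadjusted p under 0.05. That split leaves the genotype difference in its 1 residual degree of freedom. Few calls were therefore fixed in advance, and the split is no control for the paired fit.

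Genes that fell in KO cells in that paired fit included Arc, Pou4f1 and Clu. Arc, an activity-regulated cytoskeletal gene, had 2 reads in KO against 83.3 ± 11.0 CPM in WT, a ratio of 762 with a 95% Poisson interval of 211 to 6294 (edgeR adjusted p = 1.64e-06). Pou4f1 had 1 read in KO, a ratio of 385 with an interval of 69.1 to 15215 (adjusted p = 0.000467). Clu, the secreted chaperone clusterin, was 0.747 ± 0.594 against 79.4 ± 68.3 CPM (-6.66 ± 0.21, adjusted p = 2.07e-06). Genes that rose included those of the C-type lectins Cd207 (1.86 ± 0.24, adjusted p = 0.00223) and Cd209e (1.85 ± 0.29, adjusted p = 0.00618), and of the cytokine Il1b, at 61.8 ± 40.5 against 18.3 ± 10.7 CPM (1.73 ± 0.14, adjusted p = 0.000296). The receptor Hcar2 (1.71 ± 0.14, adjusted p = 0.000486) and the chemokine Ccl4 (1.63 ± 0.16, adjusted p = 0.000624) also rose. Of these 8 genes, edgeR without the block called none.

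Dendritic cell maturation genes were lower in KO than in WT cells at day 2 as a group. Their median was -1.02 (camera adjusted p = 3.52e-18; adjusted p = 0.094 with an estimated correlation), and the pairs gave -0.87 and -1.54. In the dendritic cell maturation list 20 of 22 genes were lower in both pairs. Over all genes 1 of the 22, Samsn1, was called lower, and 9 were lower adjusted over the list alone. In the paired fit 12 genes of the dendritic cell maturation list were called lower, and 16 adjusted over the list alone. Tmem123 was 396 ± 219 CPM in KO against 1629 ± 476 CPM in WT (paired -2.13 ± 0.17, edgeR adjusted p = 0.000894, against 0.184 without pairing and 0.0148 with the replicate block over all libraries). Il12b, a subunit of interleukin 12, was 1.03 ± 0.512 against 6.496 ± 0.246 CPM (paired -2.55 ± 0.38, adjusted p = 0.00427) and Socs2 295.5 ± 147 against 508 ± 204 CPM (paired -0.81 ± 0.11, adjusted p = 0.00261). Ccr7, the receptor that guides dendritic cells to lymph nodes, was 53.6 ± 62.9 against 796 ± 80.7 CPM (-3.90 ± 1.37, adjusted p = 0.965). Paired, Ccr7 was at -4.57 ± 1.48 (adjusted p = 0.324). Fscn1 was 65.2 ± 58.9 against 865 ± 189 CPM (paired -4.05 ± 1.23, adjusted p = 0.307) and Ccl22 4310 ± 1100 against 13359 ± 3700 CPM (-1.63 ± 0.56, adjusted p = 0.927).

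MHC class II genes moved in the opposite direction at day 2, with a median of 0.74 (camera adjusted p = 2.67e-05; adjusted p = 0.147 with an estimated correlation) and pairs at 0.52 and 0.90. None of the 14 MHC class II genes passed over all genes or adjusted over the list alone, and in the paired fit 9 were called higher and 10 adjusted over the list alone. Among them were March1, a ubiquitin ligase for MHC class II (1.04 ± 0.14, edgeR adjusted p = 0.00383), and Ciita, the class II transactivator (0.74 ± 0.12, adjusted p = 0.00683). H2-Ab1 was 4498 ± 666 against 2407 ± 148 CPM (paired 0.90 ± 0.14, adjusted p = 0.00534). Cd74 was 14872 ± 1700 against 10752 ± 482 CPM (0.47 ± 0.33, adjusted p = 1, and 0.0823 when paired). Macrophage genes had a median of 0.44, or 0.41 with genes at 0 at their bound (camera adjusted p = 0.00344; adjusted p = 0.676 with an estimated correlation). In the paired fit 8 of 28 macrophage genes were higher, among them Cd14 (1.02 ± 0.12, adjusted p = 0.00134) and Adgre1, the marker F4/80 (0.90 ± 0.10, adjusted p = 0.00149). Inflammatory NF-kB targets had a median of 0.88 (camera adjusted p = 0.0217; adjusted p = 0.676 with an estimated correlation; 0.0654 without the 2 libraries that stood apart). In the paired fit 11 of 24 inflammatory NF-kB targets were higher and 1 lower, with Tnf (1.32 ± 0.16, adjusted p = 0.00167) and Ccl3 (1.56 ± 0.16, adjusted p = 0.000858) among the higher.

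**Figure D3:**
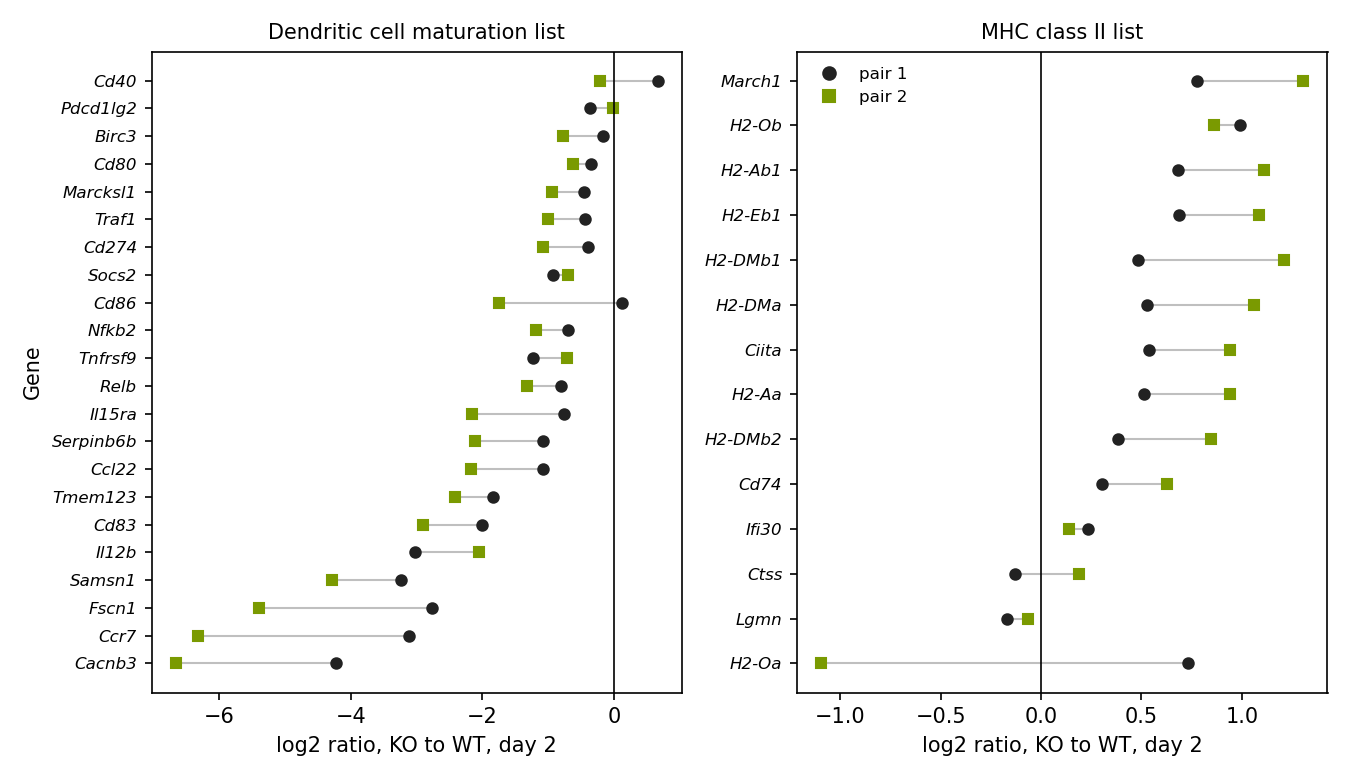
Log2 ratio of KO to WT at day 2 for each gene of the dendritic cell maturation list (22 genes) and the MHC class II list (14 genes), with a circle for pair 1 and a square for pair 2. In the maturation list 20 of 22 genes lie at negative ratios in both pairs, and in the MHC class II list 11 of 14 lie at positive ratios in both.

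Other lists past the camera threshold in KO against WT cells at day 2 were the cell cycle (0.33, adjusted p = 0.000141), the unfolded protein response (0.39, adjusted p = 0.00772) and matrix proteases (0.47, adjusted p = 0.00326). Cell cycle, unfolded protein response and matrix proteases each had adjusted p = 0.182 or more with an estimated correlation. In the paired fit Bub1b, a spindle checkpoint kinase (0.46 ± 0.11, edgeR adjusted p = 0.0267), Hspa5, the chaperone BiP (0.45 ± 0.11, adjusted p = 0.0329), and Plau, urokinase (1.12 ± 0.13, adjusted p = 0.00207), rose. Mmp12 rose there too, at 3375 ± 520 against 1474 ± 660 CPM (1.26 ± 0.16, adjusted p = 0.00347), and Adam19 fell (-0.88 ± 0.10, adjusted p = 0.00157). Mki67, a marker of cycling cells, was 448 ± 36.6 against 354 ± 21.8 CPM (0.34 ± 0.32, adjusted p = 1). Markers of granulocytes were higher in the same KO libraries. Neutrophil genes had a median of 0.74 (camera adjusted p = 0.00344; adjusted p = 0.676 with an estimated correlation) and summed to 1197 and 1955 CPM in KO against 575 and 1370 CPM in WT libraries. Eosinophil genes had a median of 1.97 (camera adjusted p = 0.000576; adjusted p = 0.273 with an estimated correlation) and summed to 225 and 758 CPM in KO against 110.4 and 385 CPM in WT libraries. Alox15, which is also in the IL-4 list, made up most of the eosinophil sum (453 ± 381 against 231 ± 198 CPM, paired 0.99 ± 0.11, edgeR adjusted p = 0.00106). Epx, eosinophil peroxidase, rose in the paired fit (3.24 ± 2.70 against 0.253 ± 0.358 CPM, 3.64 ± 0.64, adjusted p = 0.00879). Of the 9 lists past the camera threshold, dendritic cell maturation alone had a member called over all genes or adjusted over the list alone without pairing. All 9 lists lost their call with an estimated correlation and with fry, and camera called 16 lists without WT day 2 replicate 1 and 14 without KO day 2 replicate 2.

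Whether the genotypes differed more at one stage than at another was tested with interaction terms. Between day 2 and monocytes edgeR called 4 genes lower. They were Slc4a8 (-9.12 ± 0.87, adjusted p = 0.00925), Scd1 (-9.40 ± 0.97, adjusted p = 0.0195), Atmin (-2.91 ± 0.36, adjusted p = 0.0266) and Traf1 (-3.80 ± 0.47, adjusted p = 0.0266). Scd1 had 0 reads in WT monocytes, so its value depends on the prior count, and its difference at day 2 was -3.07. Traf1 was at -0.71 ± 0.25 in KO against WT at day 2 (edgeR adjusted p = 0.93) and at 3.08 ± 0.40 in monocytes (adjusted p = 0.155), where WT libraries held 0.230 and 0.211 CPM and KO libraries 2.14 and 1.77 CPM. Atmin was at -2.35 ± 0.26 at day 2 (adjusted p = 0.0189). The count was 58 without WT monocytes replicate 1, 2 without WT monocytes replicate 2, and 1 without KO monocytes replicate 1, KO monocytes replicate 2, WT day 2 replicate 1 or WT day 2 replicate 2. It was 0 without KO day 2 replicate 1, where Slc4a8 had adjusted p = 0.0584, or without KO day 2 replicate 2, where it had 0.0567. The replicate block gave 7, DESeq2 32 and a fit on the compared groups only 0. Traf1 had adjusted p = 0.154 on unstranded counts and 0.151 without the 2 libraries that stood apart. Between day 1 and monocytes edgeR called 0 genes (400 at an unadjusted p under 0.05, and 1 by DESeq2), and between day 2 and day 1 it called 0 (340 at an unadjusted p under 0.05, and 22 by DESeq2). The last count was 2 with the replicate block, 14 without KO day 1 replicate 2 and 1 without KO day 2 replicate 1. The dendritic cell maturation list was more negative in KO cells at day 2 than in monocytes (difference -1.64, camera adjusted p = 6.62e-11; adjusted p = 0.312 with an estimated correlation). It was also more negative at day 2 than at day 1 (-0.81, camera adjusted p = 6.49e-06; adjusted p = 0.385 with an estimated correlation), with -0.42 (camera adjusted p = 0.036) without the 2 libraries that stood apart.

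Genes that culture moved in WT cells were then followed in KO cells at the other day, which shares no library. The 807 genes raised and the 713 lowered in WT cells at day 1 (at least 4-fold, a log2 fold change of 2) had medians of 0.21 (camera adjusted p = 0.119) and 0.18 (camera adjusted p = 0.141) in KO against WT at day 2. Both had adjusted p = 0.721 with an estimated correlation, and the same raised genes adjusted p = 0.103 with the replicate block and 0.0369 without the 2 libraries that stood apart. Other settings drew the lists anew from their own WT calls. For the raised genes drawn anew the adjusted p was 0.0335 with the replicate block, 0.0151 without WT monocytes replicate 2, 0.0196 without WT day 1 replicate 1 and 0.00531 without WT day 1 replicate 2. It was 0.000313 without WT day 2 replicate 2 and 0.00209 without KO day 2 replicate 1, and the median was -0.04 without KO day 2 replicate 2. For the lowered genes drawn anew the adjusted p was 0.0164 without WT day 1 replicate 1, 0.000281 without WT day 2 replicate 1 and 0.00019 without KO day 2 replicate 2. Their median was -0.15 without KO day 2 replicate 1 and -0.01 without WT day 2 replicate 2. The 1147 genes raised and 651 lowered in WT cells at day 2 had medians of -0.16 (camera adjusted p = 6.39e-06) and 0.30 (camera adjusted p = 6.46e-09) in KO against WT at day 1, both with adjusted p = 0.0984 with an estimated correlation. Drawn anew without the library labelled KO day 1 replicate 1 these were -0.08 (camera adjusted p = 0.0559) and -0.02 (camera adjusted p = 0.26). The same 1147 and 651 genes had medians of -0.09 (camera adjusted p = 0.0218) and -0.01 (camera adjusted p = 0.388) without the 2 libraries that stood apart. Across 14034 genes, which are not independent replicates, the KO effects at day 1 and day 2 had a Pearson correlation of 0.056. Their Spearman correlation was 0.021, and the 4 combinations of pairs had an SD of 0.058. Within a day, pair 1 and pair 2 correlated at -0.099 at day 1 and at 0.554 at day 2. The day 1 effect did not repeat between its pairs, so the correlation between days cannot show whether the effects are unrelated.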

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

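Of the tests weighed here, those of dilution, of a label swap and of immediate early genes in a mixture were chosen only after the result was seen, as were the libraries left out together and the paired fit.

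Interaction tests singled out results whose genotype difference changed between stages. Between day 2 and monocytes these were Slc4a8 (-9.12 ± 0.87, edgeR adjusted p = 0.00925), Scd1 (-9.40 ± 0.97, adjusted p = 0.0195), Atmin (-2.91 ± 0.36, adjusted p = 0.0266) and Traf1 (-3.80 ± 0.47, adjusted p = 0.0266). The day 2 difference alone was -3.07 for Scd1, which had 0 reads in WT monocytes, and -0.71 for Traf1, which was at 3.08 in KO against WT monocytes (edgeR adjusted p = 0.155) from levels of 0.230 and 0.211 CPM in WT. Among lists (median, camera adjusted p) they were dendritic cell maturation (-1.64, 6.62e-11), MHC class II (0.54, 0.0176, and 0.0586 with the replicate block) and platelet markers (3.01, 0.0069). Between day 1 and monocytes they were dendritic cell maturation (-0.24, 0.0472, and 0.0784 with the block), the IL-4 response (-0.37, 0.0116), the GM-CSF response (-0.32, 0.0242), interferon-stimulated genes (1.47, 0.00125), lipid handling (-0.30, 0.0492, and 0.0784 with the block), immediate early genes (-0.46, 0.00442) and eosinophil markers (-1.15, 0.0492). Without the 2 libraries that stood apart these values were -0.58 (camera adjusted p = 3.01e-05) for maturation, -0.14 (0.905, tested by camera as higher) for IL-4, -0.56 (0.0325) for GM-CSF, -0.69 (0.0325) for interferon-stimulated genes, -0.24 (0.103) for lipid handling, 0.09 (0.951, tested as lower) for immediate early genes and -5.14 (0.428) for eosinophil markers. MHC class II, between day 2 and monocytes, was then at 0.20 (0.427). Between day 2 and day 1 they were dendritic cell maturation (-0.81, 6.49e-06), the IL-4 response (0.50, 0.00217), the cell cycle (0.34, 0.0395, and 0.0651 with the block), the unfolded protein response (0.50, 0.0139), immediate early genes (0.67, 0.0122), matrix proteases (0.77, 0.0193), neutrophil markers (1.08, 0.00217) and eosinophil markers (1.47, 0.000119). Without the 2 libraries these were -0.42 (0.036) for maturation, 0.15 (0.518) for IL-4, 0.28 (0.0567) for the cell cycle, 0.20 (0.106) for the unfolded protein response, 1.89 (0.000275) for neutrophil and 0.63 (0.0548) for eosinophil markers, and the others kept their calls. In that fit further lists were called, namely neutrophil markers (-1.56, 0.000155) and glycolysis (-0.37, 0.0325) between day 1 and monocytes. Between day 2 and day 1 they were MHC class II (0.78, 0.00354), macrophage (0.48, 0.02), interferon-stimulated (1.16, 0.00162) and glycolysis genes (0.24, 0.0414). No list kept its call with an estimated correlation, where the lowest adjusted p was 0.312.

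The dendritic cell maturation list was lower in KO cells at day 2, with pairs at -0.87 and -1.54. The median was -1.002 after the 4 day 2 libraries were thinned to 5905266 reads. Random thinning keeps the expected ratio between libraries, so this median cannot decide on sequencing depth. KO held fewer gene reads than WT in pair 1 (5905266 against 8770888) and more in pair 2 (12116249 against 7787493). The list was lower in both pairs, which argues against depth. Tables argue against dilution by cells that lack the genes raised by culture. The 798 genes raised at least 4-fold by culture in WT cells at day 1 had medians of 0.15 and 0.26 in the pairs. Such dilution needs values below 0, and the lower was 0.151. Dilution by cells that hold those genes but not the maturation genes was not tested. A uniform lag of the KO culture stays open, since genes rising from WT day 1 to WT day 2 had medians of -0.37 (1442 genes) and -0.28 (1346 genes), negative but short of the list's, with -0.374 as the lower. The genotype named by the design may account for the pattern and remains a hypothesis.

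The library labelled KO day 1 replicate 1 lay apart from the other day 1 libraries. Nr4a3 argues against a swap with WT day 1 replicate 1, which held 16.5 CPM of it against 6.58 CPM in the library labelled KO. It does not exclude a swap, since the KO day 2 libraries held 39.0 and 19.3 CPM of Nr4a3. For a mixture of uncultured monocytes and day 1 cells, the interferon-stimulated list had a median log2 ratio of -0.175 to the higher of both sources. Of its 37 genes, 14 lay above that source. A mixture of any share stays at or below the higher source, so this median cannot decide for or against it. The share of monocytes that the median would need was not computed. Immediate early genes then argued against freshly sorted monocytes, with an implied share of -0.0633% (3 genes) against 7.79% from classical monocyte genes (7 genes), and Fos at 2.77 CPM against 1423 CPM in KO monocytes. Cells that stayed monocyte-like in culture, a single wrong label and a real response of that culture were not tested and remain possible.

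The paired fit at day 2 called many genes, and DNA carried along with the targeted locus could be a source. Within 10 Mb of Nr4a3 on chromosome 4, 14 of 121 tested genes were called (11.6%), against 1543 of 12111 elsewhere (12.7%), Fisher's exact two-sided p = 0.785, so the called genes were not concentrated around the locus. With 1 residual degree of freedom, chance differences between the 2 experiments stay open.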

How the results depend on the processing

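The paired fits on the compared groups only, their estimated correlation and the crossed split were chosen only after the results were seen. So were unstranded counts and the fits without the 2 libraries that stood apart. The other settings were fixed beforehand. For KO against WT at day 2, 1.43% of simulated 2-fold changes were recovered without pairing, and thinning the day 2 libraries to 5905266 reads left 15 genes called against 14. Where leaving a library out leaves 1 in a group, that library is assumed to vary like the other groups. RLE and upper-quartile normalization, the lower threshold for the culture lists and unstranded counts changed no count of genes or lists by over 1.5 times and, where run for them, no call of a culture list. Upper-quartile normalization was run for counts of genes and named genes only. None of the 207 named gene results reversed in the settings run for it, and of 133 called, 19 lost the call without some library. A reversal here is a change of sign in a result called in the main fit or in the setting. Changes of sign in results called in neither were not counted. Unless stated, the cause was not tested.

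Without the low-count filter, which tests more genes, KO against WT calls were 22 higher and 18 lower in monocytes, 112 and 28 at day 1, and 8 and 134 at day 2, and interactions 115 (day 1 minus monocytes), 93 (day 2 minus monocytes) and 122 (day 2 minus day 1). DESeq2 called 1 gene higher at day 1, 1 higher and 83 lower at day 2, 1347 lower in KO day 1 against monocytes, and 1, 32 and 22 in the interactions in the same order. With only the compared groups fitted, which leaves fewer libraries to estimate the spread, edgeR called 3 genes lower in KO at day 2, 667 higher and 787 lower in WT day 1, 896 and 669 in WT day 2, 1706 lower in KO day 2 against monocytes, and 0 in the interaction of day 2 and monocytes.

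With the replicate block by experiment, KO against WT gave 0 lists in monocytes, 7 lists at day 1 and 35 genes lower at day 2. KO day 1 and day 2 against monocytes gave 1419 and 1618 genes lower, the interactions of day 2 with monocytes and with day 1 gave 7 and 2 genes, and genes raised at WT day 1, drawn anew under the block, had a median of 0.22 (camera adjusted p = 0.0335) in KO at day 2. The same 807 genes as without the block had adjusted p = 0.103, and adjusted p = 0.721 with an estimated correlation. The block by number alone gave 7 and 2 in those interactions. The paired fit on the compared groups only gave 2 genes higher, 3 lower and 2 lists in monocytes, and 8 lists at day 1. At day 2 it gave 764 genes higher, 794 lower and 16 lists. The crossed split of the day 2 libraries, whose sides each mix KO and WT, gave 0 calls in either direction. With an estimated correlation those paired fits gave 0, 0 and 0 lists, with adjusted p = 0.7503 or more at day 2, and 0 and 0 lists in WT and KO day 1 against monocytes. Beyond these counts and the genes and lists given with their blocked values, the block by experiment changed the call of erythroid genes in WT day 2 against monocytes (-1.69, camera adjusted p = 0.0347), of erythroid genes in the interaction of day 2 and monocytes (1.39, 0.0446), of oxidative phosphorylation in the interaction of day 2 and day 1 (0.19, 0.038) and of Mki67 in WT day 1 (-1.05, edgeR adjusted p = 0.0246), and no other call. These lists had adjusted p = 0.538, 0.853 and 0.941 with an estimated correlation in turn.

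With an estimated correlation, KO against WT gave 0, 0 and 0 lists in monocytes, at day 1 and at day 2, and each of the 4 comparisons with monocytes gave 1. With fry the genotype comparisons gave 0, 0 and 0. Against monocytes fry gave 17 lists in WT day 1, 17 in WT day 2, 18 in KO day 1 and 19 in KO day 2. Genes raised and lowered at WT day 2 kept medians of -0.16 and 0.30 in KO at day 1, with adjusted p = 0.0984 for both with an estimated correlation and 0.235 for both with fry.

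Without the 2 libraries that stood apart there were 4 lists in monocytes and 44 genes lower at day 2 for KO against WT, 1734 higher and 1574 lower in KO day 1, and 1844 lower in KO day 2 against monocytes. The culture lists were drawn anew there, and genes raised at WT day 1 had a median of 0.21 (camera adjusted p = 0.0082) in KO at day 2, against adjusted p = 0.0369 for the same 807 genes. Genes lowered at WT day 2, drawn anew, had a median of -0.12 (camera adjusted p = 0.0479) in KO at day 1, a reversed sign, while the same 651 genes had -0.01 (camera adjusted p = 0.388). With the block as well, KO against WT gave 7 higher and 142 lower at day 2, KO day 1 against monocytes 2202 and 2118, KO day 2 against monocytes 2921 and 2760, and the interactions of day 2 with monocytes and with day 1 1 and 1.

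Leaving out 1 library at a time, KO against WT gave 0 to 123 genes higher, 0 to 14 lower and 2 to 4 lists in monocytes. It gave 0 to 15 higher, 0 to 10 lower and 4 to 10 lists at day 1, and 0 to 0 higher, 1 to 2 lower and 8 to 16 lists at day 2. WT day 1 gave 789 to 2383 higher, 608 to 1512 lower and 15 to 16 lists, and WT day 2 972 to 2690, 522 to 1763 and 13 to 17. KO day 1 gave 303 to 1074 higher, 276 to 897 lower and 17 to 19 lists, and KO day 2 527 to 875, 400 to 560 and 15 to 19. The interactions gave 0 to 0 (day 1 minus monocytes), 0 to 58 (day 2 minus monocytes) and 0 to 14 (day 2 minus day 1). With lists drawn anew, medians of genes raised and lowered at WT day 1 ran from -0.037 to 0.29 and from -0.15 to 0.41 in KO at day 2. Those of genes raised and lowered at WT day 2 ran from -0.37 to -0.081 and from -0.018 to 0.58 in KO at day 1. The lowest of the last range, -0.018 without the library labelled KO day 1 replicate 1, reversed the sign (camera adjusted p = 0.26). The correlation of KO effects between days ran from -0.049 to 0.055.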

Other observations

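The lists, their tests and the replicate block used here were fixed beforehand, and only the fit without the 2 libraries that stood apart was chosen after the result was seen.

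Markers of cells other than monocytes were summed over each list. Erythroid markers summed to 42.0 to 163 CPM in monocytes, 2.08 to 7.08 CPM at day 1 and 56.7 to 138 CPM at day 2. B cell markers summed to 406 to 489.6 CPM in monocytes, 36.5 to 50.8 CPM at day 1 and 69.9 to 219 CPM at day 2. As a list the B cell markers had a median of 0.72 at WT day 1 (camera adjusted p = 0.984) and 0.13 at KO day 1 (camera adjusted p = 0.266), with 1 gene called higher and 1 lower in each. Platelet markers, called in no comparison of stages, summed to 98.2 and 51.6 CPM in WT monocytes and to 57.0 and 49.2 CPM in KO monocytes. Eosinophil markers stood at 4.40 to 5.47 CPM in monocytes and 110.4 to 758 CPM at day 2.

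Of the 33 lists, 11 were called in no contrast between groups. Their lowest camera adjusted p was 0.100 for NR4A genes, 0.0629 for lysosome genes, 0.0743 for heat shock genes, 0.0934 for oxidative phosphorylation and 0.106 for glycolysis. It was 0.235 for chemokine receptors, B cell, mast cell and basophil, and plasmacytoid dendritic cell markers, 0.219 for T and NK cell markers and 0.352 for progenitor markers. With the replicate block oxidative phosphorylation was called in WT day 1 (0.42, camera adjusted p = 0.0419), WT day 2 (-0.32, 0.0499) and KO day 1 against monocytes (0.53, 0.0134), and lysosome genes in WT day 1 against monocytes (-0.33, 0.0433). With an estimated correlation the first 3 had adjusted p = 0.907, 0.817 and 0.875, and lysosome genes adjusted p = 0.842. Oxidative phosphorylation medians without the 2 libraries that stood apart were 0.86 (camera adjusted p = 0.000107) in WT day 1 and 0.91 (camera adjusted p = 0.00087) in KO day 1 against monocytes. In that fit, which holds 1 KO library at day 1, its median in KO against WT cells at day 1 was 0.25. Over all libraries that median was -0.07 (camera adjusted p = 0.957 with an estimated correlation).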
